A study of Mus musculus with 6 samples.

How the data were processed

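The study measured RNA from thymic regulatory T cells of NOD and C57BL/6 (B6) mice aged 3 weeks, with 3 libraries per strain. Per the labels' protocols, total RNA was extracted with a miRNeasy micro kit and libraries were made with the TruSeq Standard Total RNA LT protocol from high-quality RNA. Such libraries hold nuclear and non-coding transcripts besides mRNA. Per the submitters' processing notes, the authors used Trimmomatic, STAR, DESeq2 and the mm10 genome build, and no versions are printed there. The counter, the gene annotation and the strand setting are not given in the sources used here. Genes that overlap on opposite strands therefore cannot be told apart with certainty, nor can near-identical copies.

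A single table was deposited, with 32801 gene symbols. Its 6 sample columns hold scores, which are read counts that the authors divided by a size factor per library, per the file headers, and rounded to whole numbers. The same deposited table gives the authors' log2 fold change and its standard error, their p-value and adjusted p-value from DESeq2, and the mean and test statistic of that comparison as further scores. The deposited mean is not the mean of the 6 columns (ratio 0.06 to 3.69 for genes above 100 normalized counts), so it does not rest on these 6 columns alone. Columns were matched to strain by name. They carry numbers that differ from the replicate numbers of the labels, so libraries are called NOD library 2, 10 and 18 and B6 library 4, 12 and 20, and no column was tied to a replicate number. No further sample columns were left unused.

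Depth was estimated from the rounding, since dividing whole reads by a factor above 1 doubles some whole numbers and by a factor under 1 skips others. The method was tested on simulated libraries with known factors, and the estimates ran from 0.8798 (B6 library 20, 15500000 reads) to 1.245 (NOD library 18, 21600000 reads). Of low values, 60.1% (NOD library 18) to 100% (B6 library 20) could have come from a single whole read count. Whole reads could not be recovered for every value, and no count test was run. The planned test was for raw counts, with limma-trend named as the test for values divided by size factors, and the latter is the test reported.

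Genes were kept with at least 10 normalized counts in at least 3 libraries (2 where a library was left out of a strain). This filter replaced the planned one, which needs raw counts, and was chosen once the unit was known. It left 16442 genes. The fit was limma 3.58.1 in R 4.3.3 (with data.table in version 1.17.8) on log2(value + 1), with strain as the only term and empirical Bayes moderation with a trend. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. Means are of normalized counts with the SD over 3 libraries, and log2 fold changes carry limma's standard error or 95% interval. The median interval, which is not adjusted for the number of genes, reached 0.45 to either side on the log2 scale. A call asks for more than an interval clear of 0. With limma, 3340 genes had an unadjusted p below 0.05 and 1626 were called. On simulated libraries of 16466 genes, 28.4% of changed genes were recovered at a fold of 1.5, 89.4% at 2 and 100% at 4. There were 10 false calls, and the raised gene list was called while 0 others were. Genes were drawn independently at a single dispersion of 0.02, and every member of that list was raised by a fold of 1.5. These rates need not hold for the real libraries, whose genes need not be independent. The list result does not show how specific the list tests are here.

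The design, its alternatives, 30 gene lists and the rule for named genes were fixed before the data were examined; the filter was not. The 28 with at least 5 tested genes were tested with camera (preset correlation 0.01), with camera with an estimated correlation, and with fry, adjusted over lists. The rule for named genes takes the 10 highest and 10 lowest fold changes among called genes with a mean above the median of tested genes, strains separated in every library and an official symbol, then up to 4 higher and 4 lower called members per list, of which fewer are printed, and the sort and identity genes. Other members that did not pass the test, Rbpj-ps3, Ptpn22, Ddx3y, Xist and mt-Rnr2 were chosen after their values were seen. So were the parent genes of copies, the receptor segments and the histone and chemokine genes of the closing section (apart from Hist1h4f and Ccl5). Some genes that the rule takes are not reported here. Coordinates and gene types come from GENCODE M21 on GRCm38, the assembly that mm10 names, joined by symbol, and 99.3% of tested symbols matched.

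The libraries were compared before they were averaged. The chi-square statistic per gene between replicates of a strain was 15.1 to 114, so no pair agreed within sampling noise. The 50 largest genes took 17.2% to 21.9% of normalized counts, and ribosomal protein genes 5.55% ± 0.46 in NOD and 5.37% ± 0.77 in B6 (SD, n = 3 each; exact two-sided permutation p = 0.8, where 0.1 is the smallest that 3 against 3 allows). Alternatives were other scalings, filters and pseudocounts, a fold threshold, the exclusion of strain-polymorphic families and the omission of each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.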

Results

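RNA sequencing measured transcript levels in regulatory T cells (Treg), the CD4+ T cells that restrain immune responses, sorted from the thymus of mice aged 3 weeks. There were 3 libraries from NOD mice, a strain that develops autoimmune diabetes spontaneously, and 3 from C57BL/6 (B6) mice, the strain of the mm10 reference genome. The cells were GFP-negative, CD4+CD8- and Thy1.1+, and the labels used here do not state what GFP or Thy1.1 report. The series concerns Treg development in the young NOD thymus and cells that recirculate to it, and the design gives a single comparison: how GFP-negative thymic Treg of NOD mice differ in gene expression from those of B6 mice. The values are read counts divided by a size factor per library and rounded, called normalized counts here, and they sum to between 16097369 and 17625903 per library. Estimated sequencing depth, from the gaps that the rounding left, ran from 15500000 reads in B6 library 20 to 21600000 in NOD library 18. Nothing in the labels says whether the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical. The Y-linked gene Ddx3y lay between 6484 and 8792 normalized counts in every library, and Xist, the transcript of the inactive X chromosome, between 0 and 25.

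Strain was the main source of variation. The first principal component held 60.8% of the variance and separated the strains, and correlations of log values between libraries were 0.973 to 0.987 within a strain and 0.933 to 0.944 between strains. Of 16442 genes tested with limma-trend, 755 were higher and 871 lower in NOD at an adjusted p below 0.05, and 981 of these differed at least 2-fold (448 higher, 533 lower). All 3 NOD libraries lay on one side of all 3 B6 libraries for 24.1% of tested genes, where chance gives 10%. The number called higher was 490 without NOD library 18, and the number called lower was 569 without B6 library 4. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values.

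Among the 10 genes with the highest fold changes that met the naming rule, 6 are processed pseudogenes or related sequences of abundant genes. Tpm3-rs7, a sequence related to the tropomyosin gene Tpm3 (chromosome 14, 113314608 to 113316754, mm10), stood at 4088 ± 227 normalized counts in NOD and 71.7 ± 18.5 in B6 (SD, n = 3 each), a log2 fold change of 5.84 ± 0.17 (SE, limma adjusted p = 6.8e-09). Tpm3 itself was lower in NOD, at 5079 ± 718 against 8631 ± 66.7. The other copies were Rps24-ps3 (log2 fold change 5.53), Rpl34-ps1 (5.14), Vcp-rs (5.08), Rps19-ps6 (4.24) and Rpl3-ps1 (4.09). Reads of such copies and of their parent genes are near-identical, and these values are uncertain for that reason. The other 4 are Alpk1, a kinase that senses bacterial sugar nucleotides (3.50 ± 0.17, adjusted p = 1.6e-07), Ypel2 (3.43 ± 0.13), Rflnb, a filamin-binding protein (3.34 ± 0.31), and Plaur, the urokinase receptor (2.93 ± 0.23). Alpk1 lies on chromosome 3 (127670310 to 127780527, mm10) and stood at 1975 ± 328 in NOD against 173 ± 29.7 in B6.

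Arhgap31, a GTPase-activating protein for Cdc42 and Rac1 (chromosome 16, 38598340 to 38713274, mm10), was among the genes that fell most in NOD. It stood at 368 ± 14 normalized counts against 6876 ± 236 in B6, a log2 fold change of -4.22 ± 0.10 (SE, limma adjusted p = 2.1e-09). Hopx, a homeodomain protein without DNA binding, fell by 3.65 on the log2 scale (190 ± 29.5 against 2390 ± 387, adjusted p = 6.8e-08). Also lower were Cpm, a membrane carboxypeptidase (-2.79 ± 0.13), Suclg2, a subunit of succinyl-CoA ligase (-2.47 ± 0.16), the histone gene Hist1h4f (-2.46 ± 0.28) and Ttn, the gene of titin (-2.44 ± 0.16). The class I gene H2-Q5 (-5.83 ± 0.21), H2-T22 (-3.39 ± 0.12), the interferon-inducible GTPase Gvin1 (-3.88 ± 0.16) and Rpl29 (-3.02 ± 0.11) complete the 10. Those 4 have close paralogs or pseudogenes with which the counting could have shared reads. All 20 genes kept their call with any single library left out.

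The genes that define the sorted population were present in every library. Foxp3, the transcription factor of the Treg lineage, stood at 2018 ± 305 normalized counts in NOD and 2061 ± 344 in B6, a log2 difference of -0.03 (95% interval -0.35 to 0.29, limma adjusted p = 0.95). Il2ra, the high-affinity chain of the IL-2 receptor, stood at 4499 ± 862 and 4942 ± 1046 (adjusted p = 0.77), and Ptprc, which encodes CD45, at 47078 ± 1025 and 44783 ± 1707 (adjusted p = 0.81). Thy1 rose in NOD, from 2725 ± 159 to 5754 ± 605 (log2 fold change 1.07 ± 0.11, adjusted p = 6.2e-05), as did Cd3e, a chain of the T cell receptor complex (0.77 ± 0.13, adjusted p = 0.0022). The cells were sorted as Thy1.1+, and the labels do not state what Thy1.1 reports. The Thy1 difference therefore cannot be told apart from one in that sort marker. Cd4 stood at 7682 ± 380 in NOD and 6189 ± 317 in B6 and did not pass the test (0.31 ± 0.10, adjusted p = 0.077), though it did without NOD library 10 (adjusted p = 0.048) and with a covariate for NOD library 10 and B6 library 12 (0.025). Cd8a was at a low level, 86.3 ± 46.0 in NOD against 15 ± 4.36 in B6 (2.31 ± 0.46, adjusted p = 0.0075), and its call was lost without NOD library 18 (adjusted p = 0.051). Cd8b1, the partner chain, stood at 129 ± 10.1 and 112 ± 17.0 (adjusted p = 0.65). Rag1, needed for receptor gene rearrangement, fell (57 ± 9.17 against 122 ± 29.1, adjusted p = 0.017), a call lost without NOD library 2 or B6 library 4 (adjusted p = 0.066 and 0.099). Rag2, with 0 to 9 normalized counts per library, was too low to be tested.

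**Figure D1:**
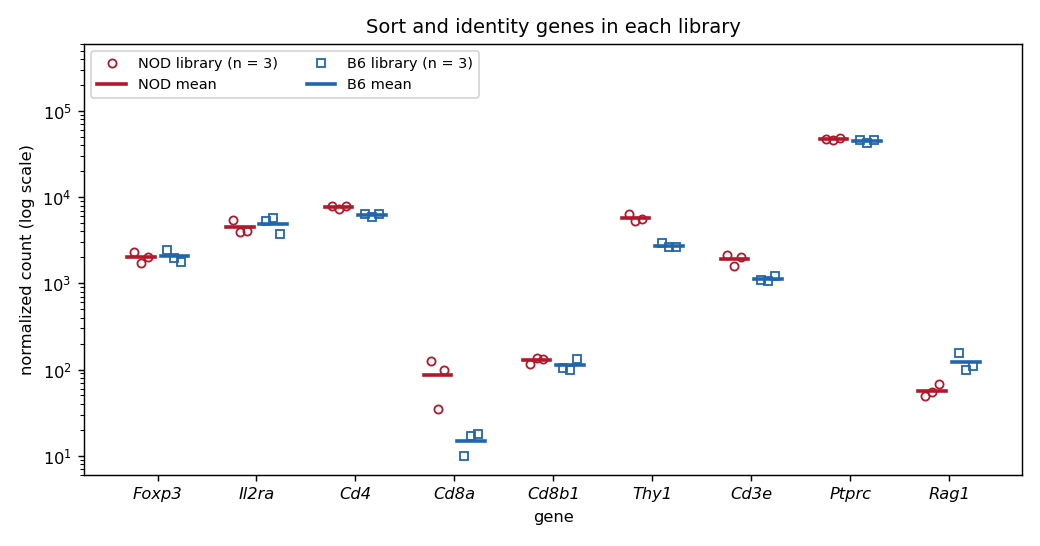
Normalized counts (log axis) of the 9 tested sort and identity genes, with a circle for each NOD library, a square for each B6 library and a bar for the mean of 3. Foxp3, Il2ra and Cd8b1 overlap between strains, Thy1, Cd3e, Cd8a, Cd4 and Ptprc lie higher in all 3 NOD libraries (Cd4 and Ptprc did not pass the test), and Rag1 lies lower in all 3.

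Genes of the Treg program moved in both directions. Of 28 core signature genes, 5 rose and 7 fell in NOD (6 and 9 when adjusted over the list alone). Nt5e, which encodes the adenosine-producing enzyme CD73, fell from 11693 ± 1025 to 4042 ± 834 normalized counts (log2 fold change -1.55 ± 0.14, limma adjusted p = 3.0e-05). Capg, an actin-capping protein (-1.17 ± 0.14), Cd83 (-1.01 ± 0.12) and the costimulatory receptor gene Tnfrsf9 (-0.78 ± 0.15) also fell. The orphan receptor gene Gpr83 rose from 145 ± 30.4 to 400 ± 69.2 (1.46 ± 0.20, adjusted p = 0.00053) and Icos, a costimulatory receptor, from 14709 ± 1414 to 23642 ± 1182 (0.69 ± 0.11, adjusted p = 0.002). Ctla4 (0.22 ± 0.12), Ikzf2 (-0.34 ± 0.14) and Tnfrsf18 (0.13 ± 0.14) did not pass the test. Of 23 suppressive mediators, 3 rose and 3 fell (3 and 6 over the list alone). Gzmb, which encodes granzyme B, rose from 1336 ± 137 to 3480 ± 943 (1.35 ± 0.18, adjusted p = 0.00056), and Lrrc32, which holds latent TGF-beta at the cell surface, fell by 0.52 on the log2 scale (adjusted p = 0.012). The call of Lrrc32 was lost without NOD library 2 or B6 library 4 (adjusted p = 0.065 and 0.059), and without B6 library 4 the core signature held 2 higher and 4 lower genes and the suppressive list 2 and 1. The core signature held 3 higher and 7 lower without B6 library 20, and the suppressive list 1 and 5 without NOD library 2.

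Of 42 effector and activation genes, 5 rose and 5 fell (7 and 8 when adjusted over the list alone). Itgb1, an integrin chain (log2 fold change 0.79 ± 0.12), rose with Gzmb and Icos, while the chemokine receptor genes Ccr6 (-1.35 ± 0.16) and Ccr8 (-0.64 ± 0.11) and the transcriptional regulator gene Id2 (-0.72 ± 0.11) fell. Of 25 genes of resting Treg and naive T cells, 4 rose and 4 fell (9 and 4 over the list alone). Igfbp4 (2.47 ± 0.28), the IL-6 receptor gene Il6ra (1.1 ± 0.12), Satb1, a chromatin organizer (0.67 ± 0.12), and S1pr1, the receptor for thymic egress (0.52 ± 0.11), rose. Ly6c2, at 1 ± 1 normalized counts in NOD and 39.3 ± 27.1 in B6, Actn1 (-0.91 ± 0.16), Sox4 and Il7r fell. Ccr7 (0.03 ± 0.13) and Bcl2 (0.05 ± 0.12), genes of the same program, did not pass the test. Without B6 library 4 the calls of Sox4 (adjusted p = 0.053) and Il7r (0.11) were lost and the resting list held 4 higher and 2 lower genes. The call of Il7r was also lost without NOD library 18 or B6 library 20 (adjusted p = 0.11 and 0.07). The effector list held 3 higher and 5 lower genes without B6 library 4 and 3 and 7 without NOD library 2. Its limma camera adjusted p was 0.93. The resting list gave 0.14, and 0.047 without NOD library 10, in a range of 0.047 to 0.25 over the omission of each library. With an estimated correlation it gave an adjusted p = 0.74 without that library.

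T cell receptor signalling genes also split. Of 32 tested, 4 rose and 6 fell (4 and 8 when adjusted over the list alone). Nfkbid, a nuclear regulator of NF-kB, fell from 1622 ± 267 to 478 ± 29.4 normalized counts (log2 fold change -1.75 ± 0.14, limma adjusted p = 1.0e-05). The immediate early genes Nr4a2 (-1.04 ± 0.17) and Nr4a3 (-0.78 ± 0.13) fell, while Nr4a1 (-0.28 ± 0.17), Egr1 (0.10 ± 0.24) and Cd69 (0.20 ± 0.18) did not pass the test. Cd200, an inhibitory ligand, rose from 856 ± 216 to 2286 ± 257 (1.44 ± 0.16). Of 43 TNF receptor, costimulation and NF-kB genes, 4 rose and 4 fell (7 and 5 over the list alone), led by Tnfrsf14, the receptor HVEM (1.60 ± 0.14, adjusted p = 1.6e-05), and Malt1 (0.75 ± 0.12) among the genes that rose. Of 29 IL-2 and STAT5 genes, 4 rose and 2 fell (4 and 3 over the list alone), including Ccnd3, which encodes a D-type cyclin (0.70 ± 0.12), and Prnp (1.13 ± 0.14), both higher. The lower calls, Il2rb and Cish, were both lost without NOD library 2, NOD library 18, B6 library 4 or B6 library 12 (adjusted p of 0.067 to 0.13), leaving 2 or 3 higher and 0 lower genes, and without NOD library 10 the list held 4 and 5. The costimulation list held 2 lower genes without NOD library 2, NOD library 18, B6 library 4 or B6 library 12. Of 38 apoptosis regulators, 2 rose and 4 fell (3 and 5 over the list alone). Bmf, a pro-apoptotic BCL2-family gene, fell from 426 ± 78.6 to 51.3 ± 4.93 (-3.01 ± 0.20, adjusted p = 2.4e-06) and Apaf1, a component of the apoptosome, from 3989 ± 216 to 1796 ± 211 (-1.16 ± 0.11), while the pro-apoptotic gene Bcl2l11 rose (0.53 ± 0.11). The apoptosis list held 1 higher and 2 lower genes without NOD library 18 and 1 and 3 without B6 library 4. None of these 4 lists passed camera (adjusted p of 0.20, 0.93, 0.93 and 0.48).

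Receptors for tissue signals and cytokines were among the called genes. Of 41 trafficking and adhesion genes, 7 rose and 5 fell (9 and 6 when adjusted over the list alone). Gpr18, a G protein-coupled receptor gene (log2 fold change 1.14 ± 0.16), and Cxcr4, the CXCL12 receptor (0.62 ± 0.12), rose with Itgb1 and S1pr1. Itgav, the integrin alpha V chain, fell from 13396 ± 519 to 6785 ± 916 normalized counts (-0.99 ± 0.12, limma adjusted p = 0.00018), as did its partner gene Itgb8 (-0.65 ± 0.15, adjusted p = 0.02), whose call was lost without NOD library 18, B6 library 4 or B6 library 20 (adjusted p = 0.11, 0.096 and 0.066). The list held 4 higher genes without NOD library 2, and 3 lower without NOD library 18 or B6 library 4. Of 24 T helper cytokine and regulator genes, 5 rose and 1 fell (6 and 3 over the list alone). Il12rb2, a chain of the IL-12 receptor, rose from 49.7 ± 9.29 to 195 ± 33.6 (1.95 ± 0.23, adjusted p = 0.00022), and Il1r1, the signalling IL-1 receptor, from 69.7 ± 17.9 to 222 ± 41.8 (1.67 ± 0.25, adjusted p = 0.00094). Il1r2, the decoy IL-1 receptor, fell from 3620 ± 331 to 2183 ± 382 (-0.74 ± 0.13, adjusted p = 0.004). Ifng (58.3 ± 17.9 against 33.7 ± 3.21) and Gata3 (1353 ± 178 against 1601 ± 161) did not pass the test. The 2 lists gave camera adjusted p of 0.48 and 0.22. The T helper list held 2 higher genes without B6 library 4, 3 without NOD library 2 or B6 library 20, and 2 lower without B6 library 12 or B6 library 20.

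Interferon response genes included members called in both directions. Of 36 interferon gamma response genes, 6 rose and 1 fell (6 and 1 when adjusted over the list alone), and all 6 encode guanylate-binding proteins, GTPases of cell-intrinsic defence. Gbp2 rose from 1534 ± 168 to 4671 ± 885 normalized counts (log2 fold change 1.60 ± 0.14, limma adjusted p = 2.4e-05), Gbp5 from 813 ± 65.4 to 1916 ± 199 (1.24 ± 0.12), Gbp3 from 3339 ± 370 to 6807 ± 1756 (1.0 ± 0.17) and Gbp7 from 2947 ± 219 to 4679 ± 289 (0.67 ± 0.10). Gvin1 was the gene that fell. Irf1 (0.18 ± 0.16), Tap1 (-0.20 ± 0.12) and B2m (-0.02 ± 0.11), also induced by interferon gamma, did not pass the test. Of 48 type I interferon genes, 7 rose and 4 fell (10 and 5 over the list alone). Slfn8 (2.83 ± 0.22, adjusted p = 8.9e-06), Ly6a (1.81 ± 0.16), Ifi204 (2.34 ± 0.32) and Mx2 (1.65 ± 0.24) rose. Ly6e (-1.96 ± 0.19) and Eif2ak2, which encodes the kinase PKR (-1.23 ± 0.14), fell, and Isg15 (0.02 ± 0.18), Irf7 (0.03 ± 0.12) and Ifit1 (0.30 ± 0.18) did not pass the test. The camera adjusted p was 0.20 for the interferon gamma list and 0.14 for the type I list. Without NOD library 18 both passed, at 0.011 and 0.003, toward higher values in NOD, in ranges of 0.011 to 0.57 and 0.003 to 0.31 over the omission of each library. Neither passed there with an estimated correlation (adjusted p = 0.65 for both). The type I list held 4 higher genes without B6 library 4, and the interferon gamma list 2 lower without NOD library 10. Gbp, Slfn, Mx, Ly6 and Ifi genes have close paralogs, and the counting could have shared their reads.

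Genes of the major histocompatibility complex (MHC), which differs in haplotype between the strains, held the largest number of calls of any list. Of 24 tested, 6 rose and 9 fell (8 and 10 when adjusted over the list alone). H2-K1 fell from 49207 ± 2796 to 20940 ± 2042 normalized counts (log2 fold change -1.24 ± 0.12, limma adjusted p = 4.3e-05) and H2-T23 from 5165 ± 89.8 to 1410 ± 194 (-1.88 ± 0.12, adjusted p = 1.4e-06). H2-T3 stood at 191 ± 15.5 in NOD and 1 ± 1.73 in B6, and H2-Q2 at 160 ± 37.0 against 14.3 ± 4.73. H2-D1 (-0.08 ± 0.17) did not pass the test. The list's median log2 fold change was -0.35 and its mean 0.29, and camera, toward lower values, gave an adjusted p of 0.22. Reads of these genes can be shared among paralogs, and alignment was to the B6 genome. Cd74, the class II invariant chain, fell from 731 ± 70.3 to 352 ± 48.0 (-1.06 ± 0.14, adjusted p = 0.00052). H2-Aa fell at a low level (51 ± 18 against 141 ± 59.8, adjusted p = 0.039), a call lost in 5 of the 6 fits with a library left out, all but the one without B6 library 12 (adjusted p of 0.052 to 0.18). Of 12 markers of dendritic cells, 4 were lower, 2 of them these same genes, 0 were higher and 8 were not called (1 higher and 5 lower when adjusted over the list alone, camera adjusted p of 0.14, adjusted p = 0.82 with an estimated correlation). The lower count was 1 without NOD library 18 or B6 library 4 and 2 without NOD library 10 or B6 library 20.

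The list of genes proposed for type 1 diabetes susceptibility (Idd) loci held 3 genes that rose and 8 that fell of 23 tested (6 and 11 when adjusted over the list alone). Nfkbid, H2-K1 and Tnfrsf9, described above, fell, as did Acadl, a long-chain acyl-CoA dehydrogenase, from 645 ± 58.3 to 217 ± 23.2 normalized counts (log2 fold change -1.57 ± 0.14, limma adjusted p = 3.0e-05), and Ptpn22, a phosphatase of receptor signalling (-0.52 ± 0.11, adjusted p = 0.0085). Icos, the kinase gene Lck (0.49 ± 0.10, adjusted p = 0.0076) and Pik3cd (0.53 ± 0.14, adjusted p = 0.032) rose, and the call of Pik3cd was lost without NOD library 2, NOD library 10, B6 library 12 or B6 library 20 (adjusted p of 0.069 to 0.11). Ctla4 and Cd28 (0.35 ± 0.11, adjusted p = 0.083) did not pass the test. The list gave a camera adjusted p of 0.14, toward lower values, and 0.82 with an estimated correlation.

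Cell cycle, metabolic and stress genes were called in differing numbers. Of 45 cell cycle genes 1 rose, E2f2 (log2 fold change 0.62 ± 0.11), and none fell (1 and 0 when adjusted over the list alone), with a limma camera adjusted p of 0.80. NOD library 10 decided this value. Its cell cycle genes lay 0.62 below their mean over all libraries on the log2 scale, with Mki67 at 2134 normalized counts against 5341 and 5182 in the other NOD libraries and 3522 to 3962 in B6. Without it the list passed with the preset correlation (adjusted p = 4.2e-06, higher in NOD) and not with an estimated correlation (adjusted p = 0.74), and 7 genes were called higher, and over the omission of each library the adjusted p ranged from 4.2e-06 to 0.88. There were 2 without B6 library 20. Glycolysis genes gave 3 higher and 3 lower of 25 (4 and 3 over the list alone), among them the glucose transporter gene Slc2a3 (0.72 ± 0.12), higher, and Pdk1 (-1.26 ± 0.16) and Ldhb (-1.01 ± 0.14), lower. Cholesterol synthesis genes gave 1 higher, Hsd17b7 (794 ± 65.5 normalized counts against 382 ± 17.1), and 1 lower of 25 (1 and 2 over the list alone), and the lower count was 0 with any single library left out. Nuclear-encoded oxidative phosphorylation genes gave 1 lower of 46, Atp5e (-0.83 ± 0.15), and 0 higher (1 lower and 0 higher over the list alone). Stress and heat shock genes gave 1 higher and 1 lower, Hspa8 (-0.92 ± 0.12), of 28 (1 and 1 over the list alone), and the higher count was 0 without NOD library 18 or any single B6 library. Fos stood at 1298 ± 356 and 1690 ± 504 and did not pass the test. Without NOD library 18 or B6 library 4 the glycolysis list held 1 higher and 2 lower genes. The stress list held 4 lower without NOD library 10. The oxidative phosphorylation list held 2 lower genes without NOD library 10 or B6 library 4, and 2 higher without B6 library 20. The camera adjusted p of these 4 lists were 0.48, 0.98, 0.52 and 0.89. NOD library 10 and B6 library 12 also held the lowest share of the mitochondrial ribosomal RNA mt-Rnr2, 1.46% and 1.79% of normalized counts against 4.88% to 7.2% in the others.

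Markers of immature thymocytes and of other cell types included called genes at low and at high levels. Of 22 double-positive thymocyte genes, 3 rose and 3 fell (4 and 4 when adjusted over the list alone), with Cd8a, Satb1 and Ephb2 (50.7 ± 16.7 normalized counts in NOD against 5 ± 4.58) higher and Rag1, Tox and Mns1 (34.7 ± 7.51 against 151 ± 21.3) lower. Without NOD library 18 the calls of Cd8a, Ephb2 and Tox were lost (adjusted p of 0.051 to 0.059), and Tox was also lost without B6 library 4 or B6 library 12 (0.12 and 0.1). The list then held 1 higher and 2 lower genes without NOD library 18 and 3 and 1 without B6 library 4. For macrophages, 1 of 9 markers was lower, Ly6c2 (3 lower over the list alone), or 2 without NOD library 18, and Lyz2 stood at 7 ± 6.93 and 28 ± 13.2. The dendritic cell list also held Ccl5 and Zbtb46 as lower genes. For B cells, 1 of 9 was higher, Ighm (log2 fold change 0.49 ± 0.10, with 1 higher and 1 lower over the list alone), and Cd79a stood at 66.7 ± 16.8 and 45.0 ± 11.8. For gamma-delta T cells, 3 of 6 were higher (3 over the list alone), namely Il23r, Sox13 (17.3 ± 4.04 against 1.67 ± 2.89) and Tcrg-C4 (17.7 ± 3.51 against 2 ± 1.73), but 0 without NOD library 18 and 1 without B6 library 4. Natural killer and innate markers gave 2 higher, Gzma and Gzmb, and 2 lower, Il2rb and Tyrobp, of 11 (4 and 3 over the list alone), and the lower count was 0 or 1 with any single library left out. Without NOD library 10 the higher count was 3, and without NOD library 2 or NOD library 18 it was 1. CD8 T cell markers gave 1 higher and 2 lower of 9 (2 and 3 over the list alone), and conventional CD4 markers 2 higher and 1 lower of 8 (4 and 1 over the list alone). The lower count was 1 for CD8 markers without NOD library 10, NOD library 18 or any single B6 library, and 0 for conventional CD4 markers without NOD library 18, B6 library 4 or B6 library 20. The CD8 higher count was 2 without NOD library 10 and 0 without NOD library 18, and the conventional CD4 higher count was 3 without B6 library 20. Thymic epithelium and stroma gave 1 lower of 9, Aire at 3.33 ± 1.53 against 16.0 ± 6.08 (1 and 1 over the list alone), a call kept without NOD library 10 and lost in the other 5 omissions (adjusted p of 0.09 to 0.14). Of the other markers named, Ighm and Tcrg-C4 lost the call without NOD library 18 (adjusted p = 0.05 and 0.07). Zbtb46 lost it without NOD library 18, B6 library 4 or B6 library 12, Ccl5 without NOD library 10, NOD library 18, B6 library 4 or B6 library 20, Il23r without NOD library 2, NOD library 18 or B6 library 4, Gzma without any single NOD library or B6 library 12, Sox13 in all omissions but that of B6 library 20 and Tyrobp in all but that of NOD library 18 (adjusted p of 0.05 to 0.19). Neutrophil and erythroid lists had 2 tested genes each and 0 calls (1 lower and 0 over the list alone), and 1 neutrophil marker was called lower without B6 library 20 or any single NOD library.

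Over all lists, 63 of 598 tested genes rose and 61 fell in NOD. None of the 28 lists with at least 5 tested genes passed limma's camera with a preset correlation of 0.01 (lowest adjusted p = 0.14), while 6 had an unadjusted p below 0.05. With an estimated correlation the lowest adjusted p was 0.82. The median, mean and camera direction of a list differed in sign for the MHC, stress, IL-2, cholesterol, B cell, stroma and CD8 lists. The fry test gave 0 lists that moved on balance one way (lowest adjusted p = 0.11). It gave 27 with genes that changed in either direction, the cell cycle list being the exception (adjusted p = 0.4). That second form asks only whether members differ between strains, not whether they differ more than other genes. With 1626 of 16442 tested genes called, it does not set these lists apart from other genes.

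**Figure D2:**
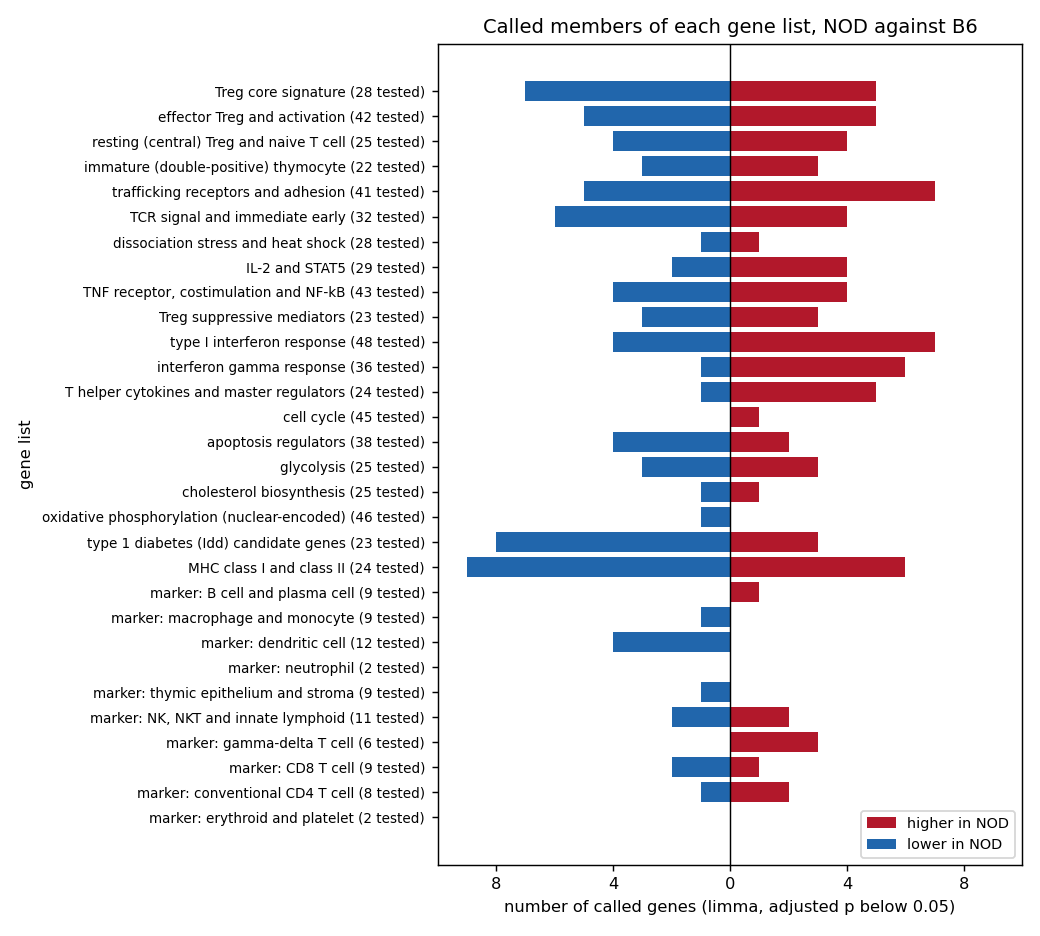
Number of genes called in each of the 30 gene lists (limma adjusted p below 0.05), with genes higher in NOD drawn to the right and genes lower to the left, and the number tested in brackets. The MHC list has 6 higher and 9 lower genes, and the interferon gamma list 6 higher and 1 lower.

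Many V segments of the T cell receptor alpha locus were lower in NOD. Of 56 tested, 22 were lower and 2 higher in NOD, and in each of the 22 every NOD library lay below every B6 library. Trav14-2 (chromosome 14, 53640701 to 53641225, mm10), Trav8-2 and Trav13-4-dv7 were listed at 0 in all 3 NOD libraries, against means of 58.7, 21.7 and 16.7 normalized counts in B6. Trav4-4-dv10 stood at 5.67 in NOD and 111 in B6. The median log2 fold change of the 22 was -3.76 (-3.46 with those 3 set at a floor of 3 normalized counts per library). Other scalings and omissions of a library gave 18 to 22 lower and 1 to 3 higher segments. The constant segment Trac fell less (log2 fold change -0.55 ± 0.11, limma adjusted p = 0.0072), and the beta constant segments Trbc1 (0.11 ± 0.12) and Trbc2 (0.25 ± 0.12) did not pass the test. Among 22 beta V segments, 3 were higher and 1 lower. These were Trbv13-1 (1.08 ± 0.16), Trbv13-2 (0.77 ± 0.16), Trbv1 (0.57 ± 0.15) and Trbv3 (-0.95 ± 0.17), named after their values were seen, as were the alpha segments. Alpha V segments have near-identical duplicates in the locus, so their reads could have been shared.

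**Figure D3:**
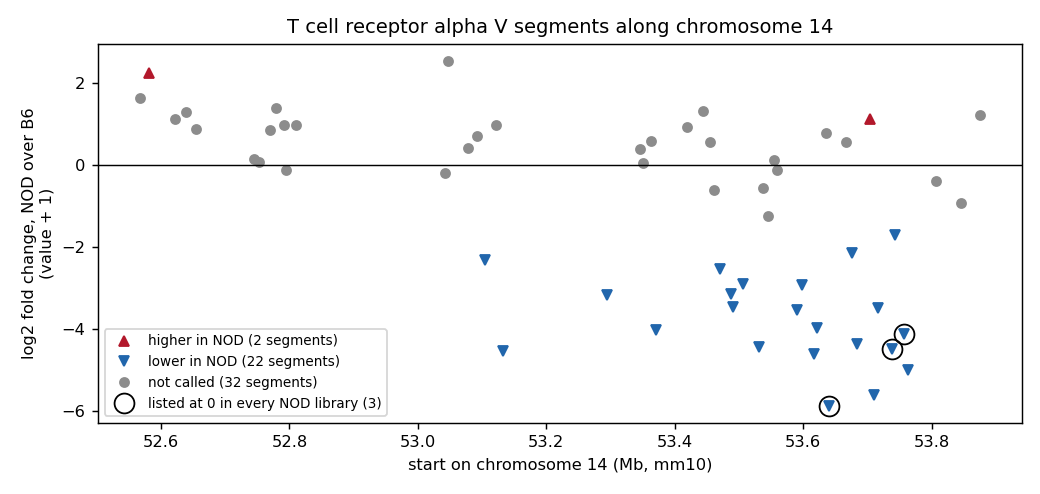
Log2 fold change (NOD over B6, value + 1) of the 56 tested T cell receptor alpha V segments by their start on chromosome 14 in Mb (mm10), with upward triangles for the 2 higher, downward triangles for the 22 lower and circles for those not called. Of the segments called lower, 18 lie between 53469756 and 53763694, and rings mark the 3 listed at 0 in every NOD library, whose plotted values depend on the added 1.

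The authors' deposited table holds its own comparison of the strains. In the authors' deposited table, 1030 genes were higher and 1113 lower in NOD at an adjusted p below 0.05, and 10813 of the 32801 symbols had no adjusted p. Of the 1626 genes called here, 1512 were also called in the authors' deposited table, each in the same direction. The deposited mean does not rest on these 6 columns alone, so the authors' test may differ in its libraries as well as its method. Some genes named above as called did not pass the authors' DESeq2 test. Among them were Ccl5 (DESeq2 adjusted p = 0.54), Lrrc32 (0.45), Cish (0.37), Ighm (0.17), Rag1 (0.13) and Tox (0.12). Gzma (0.11), Cxcr4 (0.1), Il7r (0.071), H2-Aa (0.068) and Aire (0.066) did not pass it either. Cd4, not called here, passed it (DESeq2 adjusted p = 0.015). Across the 16442 genes tested here, which are not independent replicates, the log2 fold changes of the authors' deposited table and those computed here had a correlation of 0.985. The 6 columns come from that same table, so this is not independent evidence.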

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

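Further settings chosen after seeing the data were limma-voom, a robust variance prior, protein-coding genes alone and a covariate for NOD library 10 and B6 library 12. No gene called in the main test changed direction in any of the 19 settings. Between 1526 and 1604 of the 1626 calls were kept under median-of-ratios, upper-quartile and total-count scaling, under which the median log2 fold change of all genes lay between -0.025 and 0.015, and 1585 with limma-voom. The counts were 755 higher and 871 lower. A test against a fold of 1.5 gave 287 and 325 and called 2 of the sort and identity genes in place of 4, since it asks for a larger change. A stricter filter left 10236 genes tested, with 574 called lower. The covariate gave 977 and 1088. Leaving out 1 library at a time gave 490 to 781 higher and 569 to 1011 lower, and 3 to 5 sort and identity genes. Of 126 named genes called, 54 kept the call in every setting that tested them, 85 in every omission of a library, and none reversed. Among those lost most often were Rel, Mcl1, Tnfsf11, Aldoc, H2-Aa, Aire and Tyrobp.

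No gene list passed in the main test, so no direction is called for a list. Without a filter on low values 3 lists passed, 1 of them a marker list: resting Treg, type I interferon and dendritic cell markers, each at an adjusted p of 0.036, and the cause was not tested. Across omissions of a library 0 to 3 lists and 0 to 1 marker lists passed. The adjusted p of the resting list ranged from 0.047 (without NOD library 10) to 0.25, of the type I interferon list from 0.003 (without NOD library 18) to 0.31, of the interferon gamma list from 0.011 (without NOD library 18) to 0.57, and of the cell cycle list from 4.2e-06 (without NOD library 10) to 0.88. The neutrophil list, with too few tested genes in the main test, reached 5 in some settings and passed without NOD library 18 (adjusted p = 0.041). With an estimated correlation, a setting combined with these after seeing the data, 0 lists passed in any of them (lowest adjusted p = 0.57). In the authors' deposited table, an adjusted p below 0.01 left 716 higher and 772 lower genes.

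No paired analysis was possible by the replicate numbers of the labels, because the columns carry none of them. The column numbers could be read as sets (2 with 4, 10 with 12, 18 with 20), but no label states this. A fit with a term for such guessed sets was not run, so its effect on the calls is not known. The covariate for NOD library 10 and B6 library 12 covers only the set of 10 with 12. The planned count tests, TMM factors and dispersion fit were not run, since the values are not raw counts. Depth limits genes with values below 10, such as Rag2, for which a difference was not detectable.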

Other observations

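The tests of the 3 patterns below were all chosen after the results were seen; the count over other splits of the libraries was chosen before. The test of the summed Gbp values replaced an undecided test of reads shared among the Gbp genes, and the rule of the interferon gamma test was changed once, with the same outcome. The test of the Gbp clusters was first a count of calls, which did not hold with each library left out, and was replaced by one on summed values. How the test of the parents against random lists was expressed also changed once, and a test of the cell cycle values of NOD library 10 was run and left out, so those stand in the report as values. Histone genes were lower in NOD more often than higher, with 8 lower and 1 higher of 48 tested. Hist1h3f stood at 43.3 ± 4.16 normalized counts in NOD and 418 ± 44.2 in B6 (log2 fold change -3.24 ± 0.19, limma adjusted p = 7.4e-07), and Hist1h2bg at 147 ± 23.7 and 515 ± 75.4. As a family, histones were not enriched among calls after adjustment over 232 symbol families (one-sided Fisher's exact test, adjusted p = 0.72). Alpha V segments (adjusted p = 2.9e-08), H2 genes (1.2e-07), Gbp genes (8.7e-05), Il genes (0.0017) and Cd genes (0.0027) were. Of 8 CC chemokine genes 4 were lower, at low levels, with Ccl3 at 5 ± 6.08 against 74 ± 38.4, Ccl9 at 0.333 ± 0.577 against 77.3 ± 56.8, and Ccl6 at 1.67 ± 1.53 against 38 ± 33.8 (family adjusted p = 0.14). By chromosome, 17.6% of tested genes were called on chromosome 14, which holds the alpha locus, and 13.1% on chromosome 17, which holds the MHC (two-sided Fisher's exact test over 20 chromosomes, adjusted p = 3.4e-09 and 0.021). Of 692 genes tested on chromosome 14, 30 were higher and 92 lower. Alpha V segments held 2 and 22 of these and alpha J segments 0 and 6, so they do not account for most of the calls there. The share was lower on chromosomes 19 (6.2%), 11 (7.6%) and 8 (7.1%), each with an adjusted p of 0.021.

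The 6 libraries can be split into 3 and 3 in 10 ways. The split by strain gave 1626 calls and was the 1 split with as many, and the highest of the other splits was 0 (limma-trend, with up to 2167 genes at an unadjusted p below 0.05). The splits are too few for a share under 0.05. The split with 2167 set NOD libraries 2 and 18 and B6 library 20 against NOD library 10 and B6 libraries 4 and 12, which points to a structure of the samples apart from strain. In that order of libraries, the stress and heat shock list lay at -0.26, -0.25 and -0.18 against 0.32, 0.11 and 0.27 from its mean over all libraries on the log2 scale, and the cell cycle list at 0.32, 0.33 and 0.26 against -0.62, -0.08 and -0.21.

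Processed pseudogenes were more often higher than lower in NOD, 93 against 28 of 917 tested, where protein-coding genes gave 552 and 692 (odds ratio 4.16, 95% interval 2.66 to 6.69, Fisher's exact test p = 6.5e-12); other scalings and omissions of a library gave 74 to 100 higher and 18 to 36 lower. The 14 tested parents of the copies that were higher had a median log2 fold change of -0.33, and 0 of 10000 random lists of like abundance had a median as low, which argues, for the parents as a set, against more transcription of the copies with the parents unchanged. This is consistent with reads of a NOD parent allele being assigned to a near-identical copy, though of the 14 parents 12 had a negative log2 fold change, 5 were called lower and 0 higher, and Rps19 (0.03, adjusted p = 0.95, while Rps19-ps6 gained 858 normalized counts) and Npm3 (0.305, adjusted p = 0.44) did not have a negative one. For Tpm3 the copy gained 4016 and the parent fell by 3552, while for Rbpj, which fell by 1.66 on the log2 scale, Rbpj-ps3 gained 355 while the parent fell by 4025, so this copy does not account for most of it. Copies present in the NOD genome and not in the B6 reference were not tested and stay open.

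Alpha V segments called lower lay beside each other along chromosome 14 in 14 neighbouring pairs, against 8.2 on average in random orders (permutation p = 0.002, 100000 orders). The random orders took in segments too low in B6 to be readily called lower. Among these were Trav2 and Trav7-1 (B6 means of 5 and 7.33 normalized counts), which start before every segment called lower. The pairs can thus reflect abundance in B6 as well as position, and do not by themselves show a difference in 1 stretch of the locus. Between 53469756 and 53763694, an interval chosen after the values were seen, 18 of 25 segments were lower and 1, Trav5-4, was higher. Trac, Trbc1 and Trbc2 argue against a fall of all receptor transcripts as large as that of the lower segments. Their lowest 95% bound was -0.79, where the median of the lower segments, which were picked for being lower, was -3.76. A smaller fall of alpha transcripts is not argued against, since Trac had a log2 fold change of -0.55. The 56 tested alpha V segments summed to 1007 to 1361 normalized counts in NOD libraries and 1713 to 1901 in B6. That sum, which leaves out segments below the filter, was 47.6% to 52.0% of Trac in NOD libraries and 51.2% to 52.1% in B6. These ranges overlap, so loss of NOD reads in alignment to the B6 genome cannot be told apart from reads that moved to other segments of the family. A strain difference in which segments the cells rearrange, or in which the locus holds, stays open and was not tested.

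All 5 tested Gbp genes of the cluster on chromosome 3 were higher in NOD, under other scalings and omissions of a library too, and 3 of 6 of the cluster on chromosome 5, but 0 of 6 without NOD library 2 or B6 library 4, where fewer libraries ended the calls while the median log2 fold change of the 6 (0.51) was 0.46 and 0.52. The summed values of these 6 had a log2 ratio of 0.46 (95% interval 0.21 to 0.71), with a low bound of at least 0.11 under other scalings and omissions of a library, which argues against a difference in 1 gene cluster unless reads of one cluster were counted in the other, which was not tested. Of the 28 other genes of the interferon gamma list, 25 had a 95% interval wholly below 0.67, the median log2 fold change of the 11 Gbp genes. Their own median was -0.03, where percentiles 5 and 95 of random lists of like abundance were -0.05 and 0.09. This argues against a rise of the whole list by as much as the Gbp genes. That 0 of the others were called higher carries no weight, since the Gbp genes were set apart for being called higher. A response that raised the Gbp genes more than other members is not argued against. The sum of the Gbp genes was 27270 ± 3576 normalized counts in NOD and 15149 ± 547 in B6 (log2 ratio 0.84, 95% interval 0.58 to 1.1), and alignment that loses NOD reads or moves them within the family would not raise it. Reads that are unique in NOD and shared between paralogs in B6 could raise it and were not tested.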
